A study of Mus musculus with 17 samples.

How the data were processed

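Total RNA was sequenced from E14 mouse embryonic stem cells of both genotypes (WT and RNAPII-mut) after 0, 1, 2 and 7 days of 2i added to serum and LIF medium, in 17 libraries. Groups were the 8 combinations of genotype and day, taken from the sample titles, with 2 libraries each and 3 for the mutant at day 1. The deposited values are raw gene counts, one table for all 17 libraries with gene symbols as identifiers. Per the submitters' processing notes, reads were aligned to mm10 with STAR, and deepTools was used for coverage tracks. No versions were given, and the counting tool, the annotation, the strand setting and the treatment of multi-mapping reads are not stated in the sources used here. All values in the table were whole numbers of at least 0, and 0 sample columns were left unused. Of 20621 genes, 2692 had 0 counts in every library. Library totals lay between 47350441 and 56138844 counts, and the 10 most abundant genes held 4.89 to 7.13% of a library. With such totals, 3 counts over a group of 2 libraries correspond to about 0.03 CPM, and that floor replaces a group at 0 in all its libraries when a fold change is given as a lower bound. Ratios against 1 to 3 counts carry an exact 95% counting interval. Floors and counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

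Differential expression was computed with edgeR 4.0.16 (R 4.3.3): TMM normalisation, filterByExpr on the 8 groups (15365 genes kept), one quasi-likelihood negative binomial fit over all 17 libraries with a coefficient per group, and 14 contrasts. These were mutant minus WT at each of the 4 days and on average, each later day minus day 0 within each genotype, and the difference of those responses between genotypes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast, two-sided. The common biological coefficient of variation was 0.333, with 9 residual degrees of freedom and a prior of 3.96. CPM in the text use TMM-scaled library sizes, and fold changes are from the fit, which uses a prior count, so that they differ slightly from the ratio of the mean CPM. With 2 libraries per group the fit pools the spread over groups. Where a library was left out and its group kept 1 library, that library was assumed to vary like the other groups.

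Gene lists, 30 in number and fixed beforehand, covered pluripotency states, signalling targets of the inhibited pathways, lineages and cell types that could arise or contaminate, and housekeeping, cell cycle, transcription and metabolic functions. They were tested with limma 3.58.1 camera on voom log2 CPM with a preset inter-gene correlation of 0.01, adjusted over all 420 tests, with an estimated correlation and fry as alternatives. Members are counted over all genes and adjusted over the list alone. The genes named were set by a rule: per contrast, the 5 called genes with the largest rise and the 5 with the largest fall among genes of at least 5 CPM in the higher group whose groups did not overlap (overlap allowed for the average and the differences), up to 4 called members of each list, and a fixed set of pluripotency, methylation, ERK, Wnt and lineage genes given whether or not they passed. Symbols of predicted genes were left out. The day 0 libraries' transcripts of other cell types, and the chromosomes named, were chosen after the values were seen.

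Gene spans and positions came from GENCODE M21 on GRCm38, the assembly also called mm10. A position was found for 20559 of the 20621 symbols (99.7%). Long genes were those of at least 100 kb, tested with camera against all others. Correlations across genes are Pearson's r, with 20 simulated data sets of unchanged groups for the pair of contrasts that share the WT day 0 libraries. Single values per library were compared by exact permutation.

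The 14 contrasts, the filter, the lists and their tests, the test of long genes, the correlations and the naming rule were chosen before the data were examined, but not the permutation of single values or the tests of explanations that the closing section names. So were these alternatives: DESeq2 1.42.0, 2 other normalisations, no filter and a stricter one (1 CPM in at least 4 libraries), only the compared groups in the fit, replicate number as a block, thinning to the smallest library, and leaving out each library. Added after seeing the data were a term for the WT replicate series, leaving out WT replicate 1 of days 0 and 1, offsets that remove each library's trend on gene span (span offsets), the WT series term with those offsets, leaving out genes of chromosomes 8, 15 and Y or of Y alone, and a robust prior. The procedure was tested on simulated data with 100 genes changed at each of 2-fold and 4-fold. At day 0 it recovered 11 of the 2-fold and 84 of the 4-fold changes, with 2 calls among unchanged genes. For the average it recovered 89 and 100 with 16 such calls, and for the difference in response at day 7, 3 and 31 with 1.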

Results

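RNA-seq read counts per gene were collected from E14 mouse embryonic stem cells of 2 genotypes, WT and RNAPII-mut (a slow-elongating RNA polymerase II, per the series title; "mutant" from here on). The cells grew feeder-free in 10% serum and 1000 U per mL LIF. Both inhibitors of 2i, which block MEK (1 uM PD0325901) and GSK3 (3 uM CHIR99021) and hold the cells in naive pluripotency, were added for 0, 1, 2 or 7 days. There were 17 libraries, 2 in each of 7 groups and 3 in the mutant at day 1, and 15365 genes were tested. Values are CPM (counts scaled to library size) as mean ± SD. Gene positions are on mm10.

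Libraries of a group correlated across genes at r = 0.938 to 0.971 in WT and 0.980 to 0.989 in the mutant, where genes are not independent replicates. The first principal component held 36.6% of the variance and ordered the mutant libraries by days in 2i, and the WT libraries within each replicate number but not across them. WT day 0 replicate 1 and WT day 1 replicate 1 stood apart on the second (17.02%), at 64.46 and 74.55. Both, the stromal pair, carried transcripts of mesoderm and stromal cells: T, the mesoderm regulator, was at 113 and 91.5 CPM, Acta2, smooth muscle actin, at 151 and 327 CPM, and Col1a1, a fibrillar collagen, at 54.2 and 122.6 CPM. In WT replicate 2 of day 0, T was at 0.203, Acta2 at 0.102 and Col1a1 at 1.91 CPM. That library instead held primitive endoderm transcripts, with Gata6 at 28.2 CPM against 1.24 in WT replicate 1 and 0.442 and 0.401 in the mutant. Deviations of same-numbered WT libraries from their group means correlated across genes in 6 of 6 pairs of days (r = 0.236 to 0.744). Among mutant libraries 1 of 6 pairs exceeded 0.1 (r = -0.342 to 0.174), and between genotypes 10 of 16 (r = -0.348 to 0.503).

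The genotypes at day 0 were compared in serum and LIF, before 2i. The mutation and the cell line that carries it cannot be told apart here. The mutant had less Mest, an imprinted gene expressed from the paternal allele, and less of the Y-linked genes Ddx3y (an RNA helicase), Uty (a histone demethylase homologue) and Eif2s3y (a translation initiation subunit). It had more Cds2, an enzyme of phosphatidylinositol synthesis, and more Slc12a8, a solute carrier. Transcripts of the pluripotency factors and of Polr2a, the large subunit of RNA polymerase II, did not pass the test. Mest (chromosome 6, 30723547 to 30748465) was lower in the mutant at 0.230 ± 0.0155 against 109.7 ± 8.35 CPM (SD, n = 2 and 2), 473-fold, adjusted p = 6.99e-05. Cds2 (chromosome 2, 132263148 to 132312050) was higher at 569 ± 64.85 against 209 ± 28.7 CPM (SD, n = 2 and 2), 2.72-fold, adjusted p = 0.00724, and Slc12a8 (chromosome 16) at 36.5 ± 9.38 against 10.98 ± 0.0649 CPM (SD, n = 2 and 2), 3.33-fold, adjusted p = 0.0178. Miip on chromosome 4 was 2.83-fold, adjusted p = 0.0383, higher. Neil3, a DNA glycosylase, and Ankle1, an endonuclease, both on chromosome 8, were higher by 2.59-fold and 2.57-fold. Ddx3y (630.0-fold), Uty (138-fold), Eif2s3y (28.9-fold) and the zinc finger gene Zfp951 (22.15-fold) were lower. Polr2a was at 662 ± 71.3 against 641 ± 79.9 CPM, adjusted p = 0.964, Pou5f1 at 1864 ± 43.0 against 1610 ± 377.5 CPM, Sox2 at 518 ± 20.7 against 449 ± 6.51 CPM and Nanog at 247 ± 47.6 against 316.5 ± 49.1 CPM, adjusted p = 0.566. For the de novo methylation genes, Dnmt3b was at 267.5 ± 108.5 against 417 ± 201 CPM and Dnmt3l, the catalytically inactive cofactor, at 354 ± 112 against 678 ± 495 CPM, adjusted p = 0.411. Gata6 (0.4215 ± 0.02835 against 14.7 ± 19.08 CPM, adjusted p = 0.175) and T (0.389 ± 0.188 against 56.8 ± 80.0 CPM, adjusted p = 0.173) followed the single WT libraries named above.

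Of the 30 gene lists, 9 passed the set test at day 0, and each of these 9 had adjusted p = 0.982 with an estimated correlation. The 2-cell-like list, genes of the early embryo that rare stem cells express, lay lower in the mutant (median log2 -1.26, adjusted p = 1.13e-05, or 0.0584 without WT day 0 replicate 2), with 0 of 25 members past the test and 5 lower adjusted over the list alone. Primitive endoderm genes lay lower (median log2 -2.63, adjusted p = 3.87e-05, or 0.0631 without WT day 0 replicate 2), with 0 of 22 past the test and 12 adjusted over the list alone. Trophoblast genes lay lower too (median log2 -1.57, adjusted p = 0.00581, or 0.0726 without the stromal pair and 0.164 without WT day 0 replicate 1, 3 lower adjusted over the list alone). Fibroblast and stromal genes (median log2 -2.05, adjusted p = 0.000115, or 0.468 without the stromal pair and 0.403 without WT day 0 replicate 1), cytoskeleton and adhesion genes (median log2 -0.65, adjusted p = 0.000256, or 0.561 without the stromal pair and 0.88 without WT day 0 replicate 1) and imprinted genes (median log2 -0.85, adjusted p = 0.00184, or 0.553 without the stromal pair and 0.54 without WT day 0 replicate 1) lay lower, and WT day 0 replicate 1 had the highest mean of each of these 3 lists among the day 0 libraries. Cytosolic ribosomal protein genes lay higher in 40 of 43 members (median log2 0.49 (0.27 with span offsets), adjusted p = 2.81e-06), with 1 past the test adjusted over the list alone. Oxidative phosphorylation genes lay higher in 36 of 37 (median log2 0.28 (0.15 with span offsets), adjusted p = 0.00071), as did DNA replication genes (median log2 0.14 (0.088 with span offsets), adjusted p = 0.00799, or 0.142 without the stromal pair, 0.139 without WT day 0 replicate 1 and 0.327 without mutant day 0 replicate 1). By edgeR, 43 genes passed (18 higher and 25 lower in the mutant, 40 of them at least 2-fold). The count was 3 without WT day 0 replicate 1, 110 without WT day 0 replicate 2, 1 without mutant day 0 replicate 1 and 4 without mutant day 0 replicate 2. It was 689 by DESeq2, 576 with a term for the WT replicate series, 1 with only the compared groups in the fit, and 41 (4 higher, 37 lower, 15 shared) without the stromal pair.

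At day 1, when 2i had acted for 1 day, the question was whether the genotypes differed early in the passage to the naive state. The same loci led. Mest and the Y-linked genes were lower in the mutant, and Cds2, Miip and Ankle1 were higher, joined by Elavl3, a neuronal RNA-binding protein, and Prrc1. Tcea3, a TFIIS-family elongation factor, was higher, while Krt19 (a keratin of simple epithelia), Kdr (the VEGF receptor of early mesoderm) and Sqle (squalene epoxidase of cholesterol synthesis) were lower. Elavl3 (chromosome 9, 22015005 to 22052023) was at 27.8 ± 5.945 against 6.41 ± 1.02 CPM (SD, n = 3 and 2), 4.33-fold, adjusted p = 0.00798. Cds2 was at 616 ± 48.1 against 225 ± 42.3 CPM (SD, n = 3 and 2), 2.74-fold, adjusted p = 0.00256, and Mest at 0.193 ± 0.0487 against 68.3 ± 0.420 CPM (SD, n = 3 and 2), 347-fold, adjusted p = 1.3e-05. Prrc1 was 2.67-fold, adjusted p = 0.00283, Miip 2.54-fold and Ankle1 2.38-fold higher. Tcea3 was higher at 135 ± 5.34 against 63.7 ± 2.12 CPM (SD, n = 3 and 2), 2.115-fold, adjusted p = 0.0284. Uty was 153-fold and Eif2s3y 65.4-fold lower, and Ddx3y had 2 counts over the mutant libraries and 2938 over WT, a ratio of 1910 with a 95% counting interval of 527 to 15800. Krt19 was lower at 3.11 ± 0.620 against 77.8 ± 87.5 CPM (SD, n = 3 and 2), 25.0-fold, adjusted p = 0.0237, its WT mean resting on replicate 1. Kdr was 9.36-fold, adjusted p = 0.0307, lower, from 9.091 and 2.472 CPM in WT replicates 1 and 2, and Sqle, on chromosome 15, 1.99-fold, adjusted p = 0.0411, lower, from 152.7 and 154.5 CPM. Without the stromal pair 5 of 13 calls on named genes were lost. Nanog was at 679.5 ± 134 against 667 ± 216 CPM, adjusted p = 0.976, Tfcp2l1 at 749 ± 177 against 779.6 ± 313 CPM, Pou5f1 at 2015 ± 407 against 1618 ± 946 CPM and Polr2a at 536 ± 106 against 669.6 ± 82.9 CPM. Spry4 was at 4.88 ± 5.12 against 2.89 ± 0.851 CPM, Dnmt3b at 79.4 ± 30.7 against 133 ± 37.5 CPM and Cdkn1a at 214 ± 67.6 against 242 ± 18.4 CPM, adjusted p = 0.867.

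At day 1, 10 lists passed the set test, each with adjusted p = 0.982 with an estimated correlation. Primitive endoderm genes lay lower (median log2 -2.13, adjusted p = 0.000283, or 0.243 without WT day 1 replicate 2, 10 lower adjusted over the list alone), as did trophoblast genes (median log2 -1.08, adjusted p = 0.00522, or 0.17 without the stromal pair and 0.262 without WT day 1 replicate 1, 5). Fibroblast and stromal genes lay lower with 16 of 24 past the test adjusted over the list alone (median log2 -2.82, adjusted p = 7.47e-07, or 0.0518 without WT day 1 replicate 1). Imprinted (median log2 -0.695, adjusted p = 1.08e-05), interferon-stimulated (median log2 -0.88, adjusted p = 0.00581, or 0.082 without the stromal pair and 0.1 without WT day 1 replicate 1) and cytoskeleton genes (median log2 -0.71, adjusted p = 9.01e-06, or 0.501 without the stromal pair and 0.44 without WT day 1 replicate 1) also lay lower. Ribosomal protein genes lay higher in 41 of 43 members (median log2 0.48 (0.24 with span offsets), adjusted p = 4.1e-09). Replication (median log2 0.20, adjusted p = 1.31e-05, or 0.0749 without the stromal pair and 0.0549 without WT day 1 replicate 1), oxidative phosphorylation (median log2 0.23 (0.11 with span offsets), adjusted p = 0.000115, or 0.922 without the stromal pair and 0.951 without WT day 1 replicate 1) and MYC target genes (median log2 0.14 (0.055 with span offsets), adjusted p = 0.0029, or 0.265 without the stromal pair, 0.0926 with span offsets, 0.0805 with span offsets and WT series term and 0.229 without WT day 1 replicate 1) lay higher. In all, 64 genes passed in edgeR (16 higher, 48 lower, 55 at least 2-fold). The count was 25 without WT day 1 replicate 1, 241 without WT day 1 replicate 2, 22 without mutant day 1 replicate 1, 10 without mutant day 1 replicate 2 and 16 without mutant day 1 replicate 3. It was 775 by DESeq2, 695 with the WT series term, 5 with only the compared groups and 41 (4 higher, 37 lower, 20 shared) without the stromal pair.

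Day 2 asked the same question at a later point of the transition. Elavl3, Cds2 and Prrc1 were the genes higher in the mutant, and Mest, the Y-linked genes and Aox3, an aldehyde oxidase, were lower. Elavl3 was at 23.45 ± 0.680 against 5.73 ± 1.08 CPM (SD, n = 2 and 2), 4.09-fold, adjusted p = 0.0276. Cds2 was 2.37-fold and Prrc1 2.16-fold higher. Mest was at 0.356 ± 0.1035 against 43.8 ± 28.7 CPM (SD, n = 2 and 2), 122-fold, adjusted p = 0.000507. Ddx3y was 229.7-fold, Uty 122-fold, Eif2s3y 78.4-fold and Aox3 12.8-fold, adjusted p = 0.0459, lower. Among genes that did not pass, Dnmt3l was at 35.3 ± 1.61 against 132 ± 43.35 CPM, adjusted p = 0.351, Nanog at 701 ± 45.7 against 776 ± 70.6 CPM, Tfcp2l1 at 1105 ± 67.3 against 1005 ± 18.25 CPM, Otx2 at 1.86 ± 0.740 against 3.28 ± 0.339 CPM and Polr2a at 589 ± 106 against 657 ± 276 CPM. Primitive endoderm genes lay lower in 22 of 22 members (median log2 -0.99, adjusted p = 0.000931, or 0.941 without WT day 2 replicate 2). Trophoblast (median log2 -0.67, adjusted p = 0.00799, or 0.344 without WT day 2 replicate 1 and 0.118 without mutant day 2 replicate 2), interferon-stimulated (median log2 -0.85 and -0.81 with members at their bound, adjusted p = 0.004, or 0.0572 without WT day 2 replicate 1), imprinted (median log2 -0.39, adjusted p = 0.0263, or 0.432 without WT day 2 replicate 1 and 0.173 without mutant day 2 replicate 2) and replication-dependent histone genes (median log2 -0.595, adjusted p = 0.0377, or 0.0569 without the stromal pair, 0.0521 without WT day 0 replicate 1, 0.68 without WT day 2 replicate 2, 0.0535 without WT day 7 replicate 1, 0.0536 without WT day 7 replicate 2 and 0.295 without mutant day 2 replicate 1) lay lower. Ribosomal protein (median log2 0.16, adjusted p = 0.0153, or 0.756 without WT day 2 replicate 1 and 0.586 without mutant day 2 replicate 2) and replication genes (median log2 0.063, adjusted p = 0.0153, or 0.247 without WT day 2 replicate 2 and 0.0954 without mutant day 2 replicate 1) lay higher. Each of these 7 lists had adjusted p = 0.982 with an estimated correlation. edgeR called 11 genes (3 higher and 8 lower, all at least 2-fold). The count was 3 without WT day 2 replicate 1, 5 without WT day 2 replicate 2, 1 without mutant day 2 replicate 1 and 0 without mutant day 2 replicate 2, 139 by DESeq2, 42 with the WT series term and 0 in edgeR with only the compared groups (603 at an unadjusted p under 0.05).

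Day 7 compared the genotypes once the cells had settled in 2i. Dnmt3l, which stimulates the de novo DNA methyltransferases and is repressed in the naive state, was lower in the mutant. Evc and Evc2, neighbouring ciliary genes of hedgehog signalling on chromosome 5, were both higher, as were Cds2 and Spcs3, a signal peptidase subunit on chromosome 8. Dnmt3l (chromosome 10, 78041947 to 78063622) was at 15.7 ± 2.34 against 128 ± 6.355 CPM (SD, n = 2 and 2), 8.165-fold, adjusted p = 0.0397. Evc2 (37338499 to 37425055) was at 35.1 ± 1.17 against 9.50 ± 1.09 CPM (SD, n = 2 and 2), 3.695-fold, adjusted p = 0.00278, and Evc (37289098 to 37336894) was 3.36-fold, adjusted p = 0.00278, higher. Spcs3 was 2.13-fold and Cds2 2.08-fold higher. Mest was at 0.913 ± 0.4555 against 19.4 ± 10.0 CPM (SD, n = 2 and 2), 21.2-fold, adjusted p = 0.00506. Uty (57.95-fold), Eif2s3y (41.6-fold) and Aox3 (11.99-fold) were lower. Fgf5, a marker of the primed state, had 0 counts in all 4 libraries, which allows up to 0.0275 CPM in the mutant and 0.0279 in WT. Of the naive factors, Tfcp2l1 was at 1609 ± 80.15 against 1147 ± 4.41 CPM, adjusted p = 0.609, Klf4 at 483 ± 11.5 against 452 ± 120.2 CPM, Nanog at 752 ± 67.05 against 717 ± 24.3 CPM and Zfp42 at 911 ± 60.5 against 623 ± 14.01 CPM. Dnmt3a was at 32.5 ± 6.08 against 24.8 ± 5.46 CPM, Dnmt3b at 54.1 ± 5.90 against 80.1 ± 6.18 CPM and Polr2a at 673 ± 102.5 against 721 ± 233 CPM, and none of these passed. Cholesterol biosynthesis genes lay higher in 20 of 24 members (median log2 0.47, adjusted p = 1.71e-05), with 2 past the test adjusted over the list alone. Replication-dependent histone genes (median log2 -1.47, adjusted p = 0.000223), glycolysis genes (median log2 -0.36, adjusted p = 0.00219, or 0.817 without WT day 7 replicate 1 and 0.117 without mutant day 7 replicate 2, 0 of 25 members positive), ribosomal protein genes (median log2 -0.305 (-0.14 with span offsets), adjusted p = 0.0177, or 0.592 with span offsets, 0.487 with span offsets and WT series term, 0.781 without WT day 7 replicate 2 and 0.157 without mutant day 7 replicate 1) and primitive endoderm genes (median log2 -1.78, adjusted p = 0.0269, or 0.0503 with span offsets, 0.9 without WT day 7 replicate 2 and 0.0551 without mutant day 7 replicate 2) lay lower. Each of these 5 lists had adjusted p = 0.982 with an estimated correlation. edgeR called 15 genes (4 higher, 11 lower, all at least 2-fold). The count was 6 without WT day 7 replicate 2, 2 without mutant day 7 replicate 1 and 2 without mutant day 7 replicate 2. It was 310 by DESeq2, 191 with the WT series term, 8 with replicate number as a block, 0 in edgeR with only the compared groups (1627 at an unadjusted p under 0.05) and 54 without the stromal pair.

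The average of the 4 daily differences used all 9 mutant and 8 WT libraries to ask what separated the genotypes whatever the day. Members of the primitive endoderm list were lower in the mutant, among them Col4a1 and Col4a2, the type IV collagens, Sparc, a matrix protein, Dab2, an endocytic adaptor, and the regulator Gata6. Elavl3 and Lefty2, a Nodal antagonist, were higher. Elavl3 was at 23.5 ± 10.52 against 6.58 ± 4.31 CPM (SD, n = 9 and 8), 3.59-fold, adjusted p = 1.89e-05, and Lefty2 was 3.55-fold, adjusted p = 0.00759, higher. Col4a1 was 8.07-fold, Col4a2 9.36-fold, Sparc 1.77-fold, Dab2 5.17-fold and Gata6 9.81-fold lower. Among pluripotency genes Klf2 was higher (1.74-fold, adjusted p = 0.004) and Dppa3 (3.12-fold) and Dnmt3l (3.17-fold, adjusted p = 0.000958) were lower. The imprinted genes Mest (143.5-fold), Igf2 (8.925-fold) and Nnat (24.3-fold), the glucose transporter Slc2a3 (1.61-fold) and hexokinase Hk2 (1.92-fold) were lower. Of the elongation factors, Tcea3 (1.42-fold), Hexim1 (1.37-fold), Med26 (1.355-fold) and Supt16 (1.23-fold) were higher. Over that list 5 of 44 members were higher and 1 lower (adjusted p = 0.254 for the set), and of 13 RNA polymerase II subunits 0 passed, over all genes and adjusted over the list alone.

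Primitive endoderm genes lay lower on average (median log2 -1.86 and -1.82 with members at their bound, adjusted p = 1.16e-05), with 13 of 22 past the test over all genes and 17 adjusted over the list alone. It had adjusted p = 0.982 with an estimated correlation, and its call at each single day was lost without the WT replicate 2 library of that day (0.0631, 0.243, 0.941 and 0.9). Trophoblast genes lay lower (median log2 -0.835, adjusted p = 0.00581, 5 and 10), as did fibroblast and stromal genes (median log2 -1.92 and -1.87 with members at their bound, adjusted p = 0.000448, or 0.0799 without the stromal pair, 10 and 15). Cytoskeleton (median log2 -0.43, adjusted p = 0.000256, or 0.23 without the stromal pair, 11 lower), imprinted (median log2 -0.49, adjusted p = 0.004, or 0.234 without the stromal pair and 0.0631 without WT day 1 replicate 1, 7 lower and 1 higher) and interferon-stimulated genes (median log2 -0.67 and -0.575 with members at their bound, adjusted p = 0.00854, or 0.146 without the stromal pair, 4 lower) followed. Ribosomal protein (median log2 0.23, adjusted p = 0.000355, 4 higher, Rpl5 by 1.53-fold), replication (median log2 0.081 (0.028 with span offsets), adjusted p = 0.000865, 7 higher) and oxidative phosphorylation genes (median log2 0.13 (0.077 with span offsets), adjusted p = 0.00496, or 0.322 without the stromal pair, 0.141 without WT day 1 replicate 1, 0.12 without WT day 2 replicate 1 and 0.0831 without mutant day 2 replicate 2, 2 higher) lay higher. Those other 8 lists had adjusted p = 0.982 with an estimated correlation. So did the 2-cell-like list, which lay lower (median log2 -0.42, adjusted p = 0.0283, or 0.0877 to 0.203 without any 1 of 8 libraries: replicate 2 of each WT group, mutant day 0 replicate 2 and replicate 1 of mutant days 1, 2 and 7). In total 1973 genes passed (822 higher, 1151 lower, 778 at least 2-fold). The count was 1286 without WT day 7 replicate 2, 1105 without mutant day 0 replicate 1, 1217 without mutant day 0 replicate 2, 1239 without mutant day 2 replicate 1, 1166 without mutant day 2 replicate 2, 1111 without mutant day 7 replicate 1 and 1161 without mutant day 7 replicate 2. It was 2965 by DESeq2 and 3377 with the WT series term. The fit counts the 8 WT libraries as independent, though they form 2 series. The WT series term takes their difference out of the spread, so its genotype counts may be too high.

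The genes higher in the mutant were not spread evenly over the genome. Chromosome 8 held 283 of the 820 higher genes with a position, an odds ratio of 13.7 (95% interval 11.6 to 16.3, Fisher's exact test, p = 2.41e-164, taking genes as independent). Its 819 tested genes had a median difference of 0.36 on the log2 scale, 1.28-fold, and 79.4% were positive. Klf2, Neil3, Ankle1, Spcs3 and Med26 lie there. Per library, the median deviation of chromosome 8 genes was 0.18 ± 0.046 in the 9 mutant libraries, -0.31 ± 0.025 in the 4 of WT replicate 1 and -0.084 ± 0.024 in the 4 of WT replicate 2 (SD). Chromosome 15 held 95 of 1151 lower genes (odds ratio 2.31, 1.82 to 2.91, Fisher's exact test, p = 3.32e-11), and chromosome 6, which stays in the counts below, 107 (2.21, 1.76 to 2.74, p = 2.11e-11). The chromosome 15 deviation was 0.33 ± 0.049 in WT replicate 2 and -0.12 and -0.10 in WT replicate 1 and the mutant. All 5 tested Y-linked genes were lower on average. Without chromosomes 8, 15 and Y, 1460 genes passed for the average, and 29, 40, 6 and 8 at days 0, 1, 2 and 7. The choice of these chromosomes followed from the values.

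**Figure D1:**
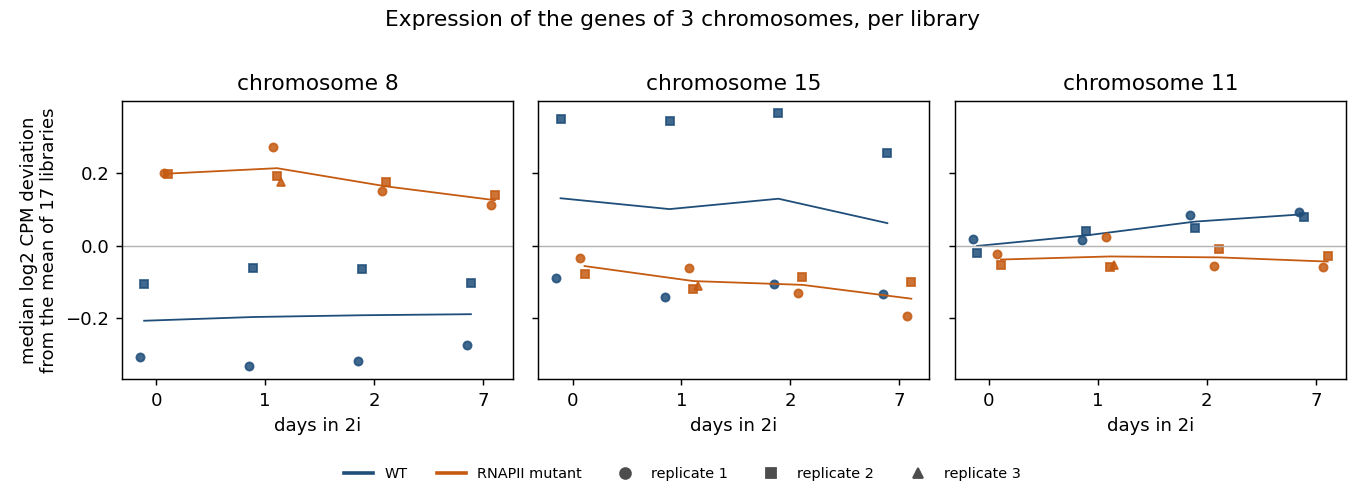
Median log2 CPM deviation from the mean of all libraries for genes of chromosomes 8, 15 and 11, by days in 2i (points are libraries, with circle, square and triangle for replicates 1, 2 and 3, and lines are group means). On chromosome 8 the mutant libraries lie between 0.11 and 0.271, above every WT library, and on chromosome 15 the WT replicate 2 libraries lie between 0.255 and 0.363.

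The WT response to 2i at day 1 shows the first transcriptional steps of the reset towards naive pluripotency. Cdx1, a target of the Wnt pathway that the GSK3 inhibitor releases, and Spic, a marker of the naive state, rose, while Utf1 and Dppa4, chromatin-bound pluripotency factors, fell. Targets of ERK and formative genes lay lower as sets (adjusted p = 0.982 for both with an estimated correlation), with 0 members of either past the test alone. Cdx1 (chromosome 18, 61018862 to 61036199) rose to 70.6 ± 31.2 against 4.94 ± 3.01 CPM (SD, n = 2 and 2), 14.3-fold, adjusted p = 0.021. Spic rose at 21.25 ± 17.7 against 1.60 ± 0.298 CPM (SD, n = 2 and 2), 13.3-fold, adjusted p = 0.021. Lrrc15 (7.95-fold), the autophagy receptor Calcoco2 (6.65-fold) and the transporter Slc16a9 (6.01-fold) also rose. Utf1 fell at 42.5 ± 3.86 against 406 ± 148 CPM (SD, n = 2 and 2), 9.55-fold, adjusted p = 0.0274, and Dppa4 1.96-fold, adjusted p = 0.048. Enpp3, an ectonucleotidase, fell 20.96-fold, adjusted p = 0.021, and Myrf (10.85-fold), Crocc2 (6.35-fold) and the amino acid transporter Slc7a7 (5.34-fold) fell as well. Not past the test were Nanog (667 ± 216 against 316.5 ± 49.1 CPM, adjusted p = 0.101), Tfcp2l1 (779.6 ± 313 against 276 ± 44.8 CPM, adjusted p = 0.0506), Spry4, the ERK feedback inhibitor (2.89 ± 0.851 against 204 ± 139.9 CPM, adjusted p = 0.0506), Otx2, the formative regulator (3.08 ± 0.244 against 25.1 ± 15.6 CPM, adjusted p = 0.0528) and Dnmt3b (133 ± 37.5 against 417 ± 201 CPM, adjusted p = 0.206).

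Naive pluripotency genes lay higher at day 1 (median log2 0.43, adjusted p = 0.00241, or 0.819 without WT day 0 replicate 1 and 0.728 without WT day 1 replicate 2), with 1 of 26 past the test and 5 adjusted over the list alone. Formative and primed genes lay lower (median log2 -0.80, adjusted p = 7.07e-06, or 0.164 without WT day 0 replicate 1), with 0 of 30 past the test and 8 adjusted over the list alone. ERK feedback and immediate early genes lay lower (median log2 -0.75, adjusted p = 1.03e-08, 0 of 25 and 5 adjusted over the list alone). Core pluripotency genes lay lower (median log2 -0.65, adjusted p = 0.00184, or 0.17 without the stromal pair and 0.262 without WT day 1 replicate 1, 2 of 11), and so did germline genes (median log2 -0.37, adjusted p = 0.0209, or 0.914 without WT day 0 replicate 2 and 0.824 without WT day 1 replicate 1). Wnt targets (median log2 0.35, adjusted p = 0.0295, or 0.746 without WT day 0 replicate 2 and 0.546 without WT day 1 replicate 1), ribosomal protein genes (median log2 0.40 (0.235 with span offsets), adjusted p = 0.000152, or 0.871 without WT day 1 replicate 2) and oxidative phosphorylation genes (median log2 0.36, adjusted p = 1.13e-05, or 0.831 without WT day 1 replicate 2, 37 of 37 positive) lay higher. Each of these 8 lists had adjusted p = 0.982 with an estimated correlation. In all 31 genes passed in edgeR (20 higher, 11 lower, 30 at least 2-fold). The count was 80 without WT day 0 replicate 1, 2 without WT day 0 replicate 2, 83 without WT day 1 replicate 1 and 0 without WT day 1 replicate 2. It was 321 by DESeq2, 237 with the WT series term and 0 in edgeR with only the compared groups (482 at an unadjusted p under 0.05).

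By day 2 the WT cells had raised several naive factors and lowered the de novo methyltransferases. Nanog (2.45-fold, adjusted p = 0.019), Tfcp2l1 (3.64-fold) and Prdm14, which represses the methyltransferase genes (3.255-fold), rose. Dnmt3a (4.21-fold), Dnmt3b (4.63-fold), Dnmt3l (5.15-fold), Otx2 (7.65-fold), Myc (9.63-fold) and the ETS factor Etv4 (22.5-fold) fell. Spry4 fell at 1.14 ± 0.457 against 204 ± 139.9 CPM (SD, n = 2 and 2), 178-fold, adjusted p = 0.00995, and Trpm1, an ion channel, rose at 249 ± 86.1 against 5.65 ± 6.65 CPM (SD, n = 2 and 2), 44.05-fold, adjusted p = 0.0126. Of the formative list 6 of 30 members fell (13 adjusted over the list alone) and the set lay lower (median log2 -1.62, adjusted p = 1.12e-07), and of the ERK list 5 fell (10 adjusted over the list alone, median log2 -1.38, adjusted p = 8.39e-09). Naive genes lay higher (4 and 8, median log2 0.71, adjusted p = 7.65e-05, or 0.106 without WT day 0 replicate 1). MYC targets (median log2 -0.22, adjusted p = 0.00105), core pluripotency (median log2 -0.715, adjusted p = 0.0153, or 0.0944 without WT day 0 replicate 2 and 0.0711 without WT day 2 replicate 2), imprinted (median log2 -0.43 (-0.67 with span offsets), adjusted p = 0.0209, or 0.613 without the stromal pair, 0.639 without WT day 0 replicate 1 and 0.238 without WT day 2 replicate 2) and cytoskeleton genes (median log2 -0.70, adjusted p = 0.00554, or 0.364 without the stromal pair, 0.612 without WT day 0 replicate 1 and 0.151 without WT day 2 replicate 2) lay lower. Ribosomal protein (median log2 0.44 (0.27 with span offsets), adjusted p = 0.00219, or 0.528 without WT day 2 replicate 2) and oxidative phosphorylation genes (median log2 0.43 (0.25 with span offsets), adjusted p = 0.000924, or 0.59 without WT day 2 replicate 2) lay higher. Each of these 9 lists had adjusted p = 0.982 with an estimated correlation. In all 332 genes passed (179 higher, 153 lower). The count was 194 without WT day 0 replicate 1, 107 without WT day 0 replicate 2 and 36 without WT day 2 replicate 2, and 1221 by DESeq2, 1489 with the WT series term and 0 in edgeR with only the compared groups (1169 at an unadjusted p under 0.05).

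At day 7 the WT comparison shows expression after prolonged 2i. Tfcp2l1, Prdm14, Klf4, Nanog and Spic, transcription factors of naive pluripotency, had risen, and the 3 de novo methylation genes had fallen. Targets of ERK, which PD0325901 silences, fell: Spry4, Dusp4 and Dusp6. Cdkn1a, the p21 inhibitor of the cell cycle, rose, while Myc and the imprinted inhibitor Cdkn1c fell. Tfcp2l1 rose to 1147 ± 4.41 against 276 ± 44.8 CPM (SD, n = 2 and 2), 4.15-fold, adjusted p = 0.00105, and Nanog to 717 ± 24.3 against 316.5 ± 49.1 CPM (SD, n = 2 and 2), 2.265-fold, adjusted p = 0.00847. Prdm14 (4.15-fold), Klf4 (2.985-fold) and Spic (28.6-fold) rose. Dnmt3a fell to 24.8 ± 5.46 against 182 ± 4.54 CPM (SD, n = 2 and 2), 7.34-fold, adjusted p = 0.000633, Dnmt3b 5.20-fold and Dnmt3l 5.28-fold. Spry4 fell to 1.17 ± 0.0156 against 204 ± 139.9 CPM (SD, n = 2 and 2), 174-fold, adjusted p = 0.00295, Dusp4 75.65-fold and Dusp6 14.7-fold. Fgf5 fell from 16.95 and 0.3045 CPM to 0 counts, at least 309-fold lower in the mean, which rests on WT day 0 replicate 1, against a floor of 3 counts over the group. Pou3f1, a formative factor, fell 53.9-fold. The Wnt targets Cdx1 (19.05-fold) and Axin2 (3.415-fold) rose. Cdkn1a rose to 368 ± 106 against 84.2 ± 45.2 CPM (SD, n = 2 and 2), 4.37-fold, adjusted p = 0.00477, and Myc (10.4-fold) and Cdkn1c (15.4-fold) fell. Tnni1, a troponin, rose from 0.0846 CPM, by 214-fold, adjusted p = 0.000927. The homeobox genes Tlx2 (58.85-fold) and Crxos (50.2-fold) and the channels Pkd2l1 (58.9-fold) and Trpm1 (46.1-fold) rose too. Otx2 (8.90 ± 3.21 against 25.1 ± 15.6 CPM, adjusted p = 0.0838), Esrrb (968 ± 42.8 against 644 ± 255 CPM), Zfp42 (623 ± 14.01 against 693 ± 285 CPM), Pou5f1 (2010 ± 332 against 1610 ± 377.5 CPM) and Sox2 (585 ± 124 against 449 ± 6.51 CPM) did not pass.

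Naive genes lay higher at day 7 (median log2 0.65, adjusted p = 0.000363, or 0.0543 without WT day 0 replicate 1), with 7 of 26 risen over all genes and 9 adjusted over the list alone. Formative genes lay lower (median log2 -2.13, adjusted p = 8.92e-06), with 11 of 30 fallen and 15 adjusted over the list alone. ERK targets lay lower (median log2 -1.77, adjusted p = 9.23e-07, 10 and 11 of 25). MYC targets (median log2 -0.35, adjusted p = 0.000143, 6 fallen) and core pluripotency genes (median log2 -0.905, adjusted p = 0.0364, or 0.116 without WT day 0 replicate 2 and 0.0917 without WT day 7 replicate 2, 5 fallen and 1 risen) lay lower, Utf1 7.61-fold and Lin28a 5.085-fold among them. Imprinted (median log2 -1.25, adjusted p = 0.00225, or 0.0562 without the stromal pair and 0.0621 without WT day 0 replicate 1, Mest 5.65-fold lower), fibroblast and stromal (median log2 -2.48, adjusted p = 0.00777, or 0.434 without the stromal pair and 0.384 without WT day 0 replicate 1) and cytoskeleton genes (median log2 -0.94, adjusted p = 0.00244, or 0.801 without the stromal pair and 0.787 without WT day 0 replicate 1) lay lower against a day 0 group whose replicate 1 held stromal transcripts. Ribosomal protein (median log2 0.62 (0.29 with span offsets), adjusted p = 0.000374, or 0.151 without WT day 7 replicate 2, 41 of 43 positive) and oxidative phosphorylation genes (median log2 0.50 (0.29 with span offsets), adjusted p = 0.0022, or 0.0859 without WT day 7 replicate 2) lay higher. These 10 lists had adjusted p = 0.982 with an estimated correlation. Of 23 Wnt targets 5 rose and 4 fell (adjusted p = 0.603 for the set, median 0.15 but mean -0.16 on the log2 scale). In all 1955 genes passed (1017 higher, 938 lower, 1601 at least 2-fold). The count was 825 without WT day 0 replicate 1, 742 without WT day 7 replicate 1 and 954 without WT day 7 replicate 2. It was 3198 by DESeq2, 4007 with the WT series term, 133 with only the compared groups and 1220 without the stromal pair.

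**Figure D2:**
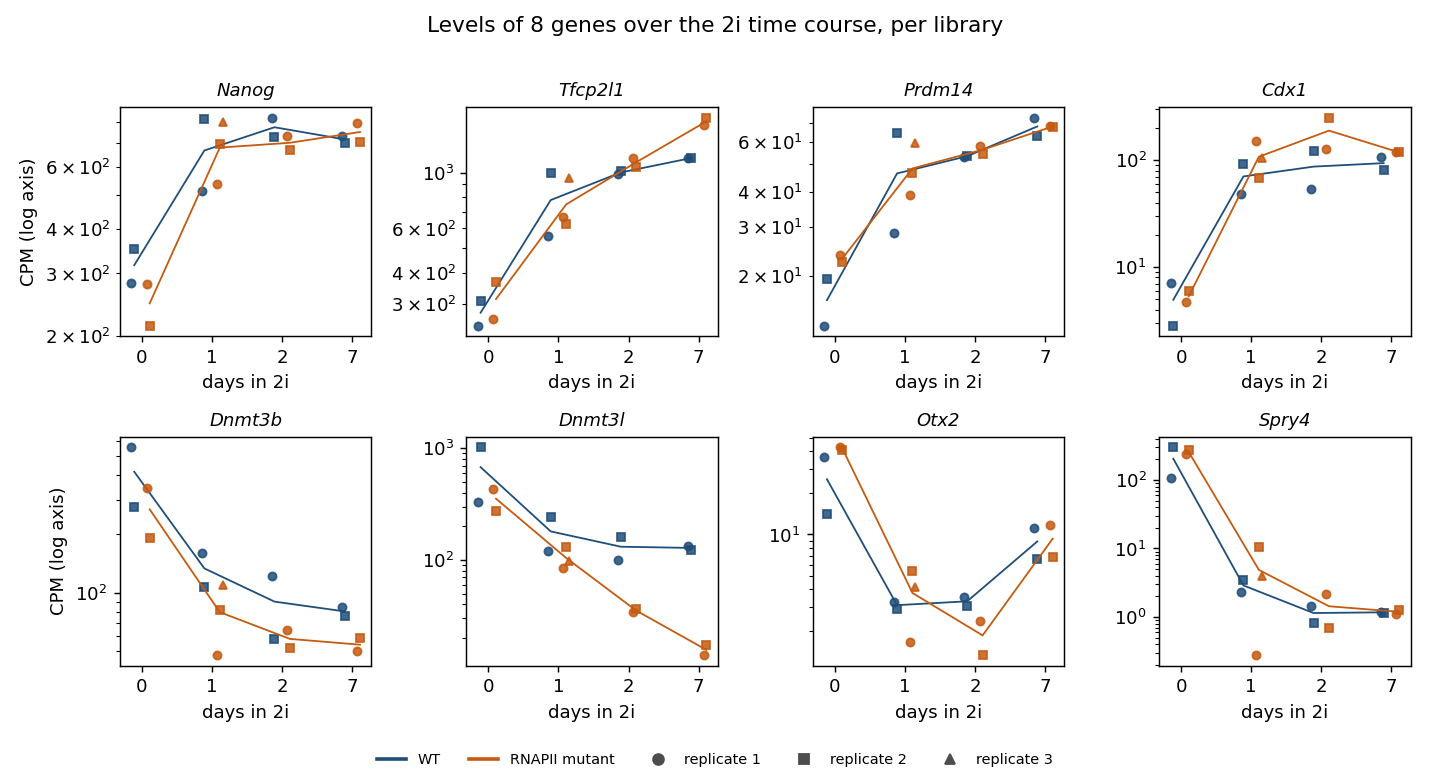
CPM on a log axis of 8 genes by days in 2i in WT and mutant (points are libraries, with circle, square and triangle for replicates 1, 2 and 3, and lines are group means). Nanog, Tfcp2l1, Prdm14 and Cdx1 rise and Dnmt3b, Dnmt3l, Otx2 and Spry4 fall in both genotypes, and Dnmt3l at day 7 lies at 14.1 and 17.4 CPM in the mutant and 133 and 124 CPM in WT.

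The mutant response at day 1 addresses how the slow polymerase cells begin the same transition. Nanog, Tfcp2l1 and Cdx1 rose, and Spry4, Etv4 and Otx2 fell. Cdkn1a rose and E2f2, a driver of S phase entry, fell. Nanog rose to 679.5 ± 134 against 247 ± 47.6 CPM (SD, n = 3 and 2), 2.75-fold, adjusted p = 0.00917, Tfcp2l1 to 749 ± 177 against 313 ± 73.7 CPM (SD, n = 3 and 2), 2.39-fold, adjusted p = 0.0345 and Cdx1 to 108 ± 41.1 against 5.31 ± 0.8455 CPM (SD, n = 3 and 2), 20.3-fold, adjusted p = 0.00362. Spic rose 5.59-fold, S100a13 20.1-fold, Trpm1 19.11-fold, the lipid droplet protein Cidea 19.07-fold and Acsm4 16.6-fold. Spry4 fell to 4.88 ± 5.12 against 256 ± 28.1 CPM (SD, n = 3 and 2), 52.3-fold, adjusted p = 0.0113, and Otx2 to 3.77 ± 1.93 against 41.9 ± 1.60 CPM (SD, n = 3 and 2), 11.1-fold, adjusted p = 0.00511. Etv4 (24.6-fold), Enpp3 (27.0-fold), Robo4 (16.9-fold), Wt1 (16.8-fold), Utf1 (8.77-fold), Dppa4 (2.18-fold), Dnmt3a (2.90-fold) and Bmp4 (3.18-fold) fell. Cdkn1a rose 3.61-fold, adjusted p = 0.0266, and E2f2 fell 3.44-fold. Dnmt3b (79.4 ± 30.7 against 267.5 ± 108.5 CPM, adjusted p = 0.0524), Dnmt3l (104 ± 23.1 against 354 ± 112 CPM), Dusp6 (9.43 ± 6.605 against 78.8 ± 12.1 CPM) and Prdm14 (48.3 ± 10.4 against 23.1 ± 0.865 CPM) did not pass. Naive genes lay higher (median log2 0.29, adjusted p = 0.00533, 3 of 26 risen and 6 adjusted over the list alone). Formative (median log2 -0.885, adjusted p = 1.57e-05, 5 and 10 of 30 fallen) and ERK genes (median log2 -0.91, adjusted p = 4.82e-08, 5 and 10 of 25) lay lower. Core pluripotency (median log2 -0.23, adjusted p = 0.00222) and interferon-stimulated genes (median log2 -0.67, adjusted p = 0.00491, Parp14 4.03-fold lower) also lay lower. Ribosomal protein (median log2 0.40 (0.21 with span offsets), adjusted p = 7.07e-06, 43 of 43 positive) and oxidative phosphorylation genes (median log2 0.345, adjusted p = 2.22e-05) lay higher. These 7 lists had adjusted p = 0.982 with an estimated correlation. edgeR called 216 genes (106 higher, 110 lower, 196 at least 2-fold). The count was 1 without mutant day 0 replicate 1, 30 without mutant day 0 replicate 2, 61 without mutant day 1 replicate 1, 113 without mutant day 1 replicate 2 and 69 without mutant day 1 replicate 3. It was 805 by DESeq2, 821 with the WT series term, 116 with replicate number as a block, which ended 10 of 26 calls on named genes, and 1077 with only the compared groups.

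At day 2 in the mutant, Nanog (2.84-fold), Tfcp2l1 (3.53-fold), Cdx1 (35.7-fold) and Cdkn1a (3.90-fold) stayed above day 0. Spry4 fell at 1.44 ± 1.06 against 256 ± 28.1 CPM (SD, n = 2 and 2), 177.5-fold, adjusted p = 0.00689. Otx2 (22.5-fold), Dnmt3l (10.0-fold), Dnmt3b (4.62-fold), Dusp6 (16.1-fold) and Etv4 (58.6-fold) fell. Crxos (63.15-fold), Tlx2 (48.8-fold) and Ly6a (38.8-fold) rose. Formative (median log2 -1.04, adjusted p = 2.9e-06, 8 of 30 fallen and 10 adjusted over the list alone), ERK (median log2 -1.05 and -1.03 with members at their bound, adjusted p = 2.69e-08, 7 and 10), core pluripotency (median log2 -0.52, adjusted p = 9.56e-06), MYC target (median log2 -0.13, adjusted p = 0.015, or 0.834 without mutant day 0 replicate 1 and 0.09 without mutant day 2 replicate 1) and p53 target genes (median log2 -0.22, adjusted p = 0.0257, or 0.0503 with span offsets, 0.068 without mutant day 0 replicate 1 and 0.0726 without mutant day 2 replicate 2) lay lower. Naive (median log2 0.37, adjusted p = 0.00581) and 2-cell-like genes (median log2 1.15 and 1.11 with members at their bound, adjusted p = 0.000579, or 0.066 without mutant day 2 replicate 2) lay higher. Each of these 7 lists had adjusted p = 0.982 with an estimated correlation. In all 449 genes passed (263 higher, 186 lower). The count was 45 without mutant day 0 replicate 1, 107 without mutant day 0 replicate 2, 103 without mutant day 2 replicate 1 and 67 without mutant day 2 replicate 2, and 1220 by DESeq2, 1331 with the WT series term and 1748 with only the compared groups.

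After 7 days in the mutant, 6 of 26 naive, 9 of 25 2-cell-like and 7 of 24 cholesterol genes had risen (set tests at adjusted p = 0.982 with an estimated correlation). Tfcp2l1, Klf4, Nanog and Prdm14 rose, and Dnmt3l, Dusp6, Spry4 and Utf1 fell. Pramel6, Pramel7 and Zscan4 genes of telomere maintenance led the 2-cell-like list. Tcea3, which was above WT at day 1, fell. Tfcp2l1 rose to 1609 ± 80.15 against 313 ± 73.7 CPM (SD, n = 2 and 2), 5.14-fold, adjusted p = 0.000333, Nanog to 752 ± 67.05 against 247 ± 47.6 CPM (SD, n = 2 and 2), 3.04-fold, adjusted p = 0.0012 and Klf4 to 483 ± 11.5 against 114.5 ± 12.01 CPM (SD, n = 2 and 2), 4.22-fold, adjusted p = 0.00118. Prdm14 (2.95-fold) and Spic (13.65-fold) rose. Dnmt3l fell to 15.7 ± 2.34 against 354 ± 112 CPM (SD, n = 2 and 2), 22.5-fold, adjusted p = 0.000294, Dnmt3a 4.39-fold, Dnmt3b 4.94-fold, Otx2 4.49-fold, Spry4 215-fold, Dusp6 22.6-fold and Utf1 22.3-fold. Cdx1 (22.3-fold) and Axin2 (5.78-fold) rose. Cdkn1a rose to 369 ± 22.6 against 59.4 ± 11.45 CPM (SD, n = 2 and 2), 6.21-fold, adjusted p = 0.00101, and Cdkn1c (11.9-fold) and Myc (6.43-fold) fell. Pramel6 rose 79.1-fold, adjusted p = 0.004, Zscan4f 4.94-fold, Zscan4c 4.73-fold and Rxra 2.23-fold. Pramel7 had 0 counts in the mutant at day 0 and was at least 53-fold higher at day 7. It then stood at 1.52 CPM, beside 1.29 CPM in WT already at day 0. The same floor gave Htr5a, a serotonin receptor, at least 418-fold higher, Obox6, an oocyte homeobox gene, at least 217-fold higher and Tmem54, at 0 on day 7, at least 219-fold lower. Nsdhl (1.68-fold), Sqle (1.775-fold) and Fdft1 (1.62-fold) of cholesterol synthesis rose. Tcea3 fell to 35.1 ± 3.37 against 182 ± 43.45 CPM (SD, n = 2 and 2), 5.19-fold, adjusted p = 5.42e-05, and Aff1, a super elongation complex subunit, rose 4.81-fold. T was at 23.0 ± 9.13 against 0.389 ± 0.188 CPM, adjusted p = 0.074.

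Of the 2-cell-like list 9 of 25 members rose in the mutant by day 7 (17 adjusted over the list alone), all 25 were positive, and the set lay higher (median log2 2.22, adjusted p = 4.99e-06). Cholesterol genes lay higher (median log2 0.625, adjusted p = 0.00071, 7 and 8 of 24 risen). Naive genes lay higher (median log2 0.38, adjusted p = 0.00784, 6 risen), and formative (median log2 -1.61, adjusted p = 0.000857, 10 fallen and 2 risen), ERK (median log2 -1.42, adjusted p = 3.88e-05, 11 fallen) and core pluripotency genes (median log2 -0.76, adjusted p = 0.000447, 5 fallen) lay lower. MYC targets (median log2 -0.41, adjusted p = 3.16e-05, 7 and 13 of 38 fallen) and replication-dependent histones (median log2 -1.30, adjusted p = 0.000913, 3 fallen) lay lower. These 8 lists had adjusted p = 0.982 with an estimated correlation. In all 2176 genes passed (1107 higher, 1069 lower, 1786 at least 2-fold). The count was 680 without mutant day 0 replicate 1, 1099 without mutant day 0 replicate 2, 816 without mutant day 7 replicate 1 and 884 without mutant day 7 replicate 2. It was 3308 by DESeq2, 3857 with the WT series term and 5556 with only the compared groups.

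**Figure D3:**
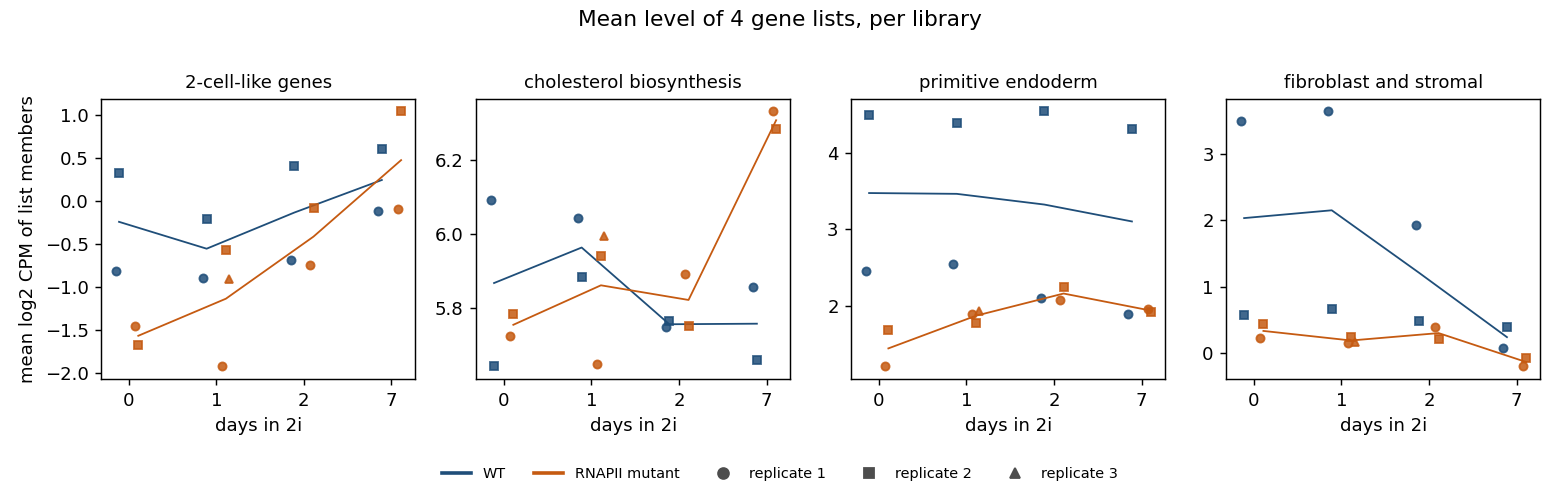
Mean log2 CPM of the 2-cell-like, cholesterol, primitive endoderm and fibroblast and stromal lists by days in 2i (points are libraries, with circle, square and triangle for replicates 1, 2 and 3, and lines are group means). The fibroblast and stromal mean is 3.50 and 3.64 in WT replicate 1 at days 0 and 1 and 0.57 and 0.66 in WT replicate 2, and the 2-cell-like mean is -1.46 and -1.68 in the mutant at day 0.

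Whether the genotypes answered 2i differently was tested gene by gene as the difference of the responses. No gene passed in edgeR at day 1, 2 or 7 (0, 0 and 0 of 15365), with 118, 366 and 1178 genes at an unadjusted p under 0.05 and 0, 0 and 73 past DESeq2's test. The WT series term gave 14 genes at day 7, among them Ddx3y, Mest, Cdh3 and Ly6a, named after their values were seen. Y-linked genes, at a median log2 of -7.11 against WT at day 0, rose in the mutant by day 7 (2.08, 2 of 5 called). Mest started low too. For Dnmt3l, 22.5-fold lower in the mutant and 5.28-fold lower in WT at day 7, the difference of -2.09 on the log2 scale had adjusted p = 0.539. In the set test the 2-cell-like list lay higher in the mutant response at days 1, 2 and 7, and cholesterol genes at day 7, while ribosomal protein genes lay lower at days 2 and 7. Their values are in the closing section, each with adjusted p = 0.982 with an estimated correlation. Of 420 set tests (30 lists in 14 comparisons), 109 passed with the preset correlation, 0 with an estimated one and 0 by fry.

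To ask how alike the responses were, they were compared across genes. The log2 fold changes correlated at r = 0.722, 0.709 and 0.75 at days 1, 2 and 7 over 15365 genes, which are not independent replicates, with orthogonal slopes (mutant on WT) of 1.18, 1.01 and 1.06. Without WT day 1 replicate 2 the day 1 value was 0.431. At day 7, 565 genes rose in both, where 73.3 would by chance, 552 fell in both (65.3), and 1 moved in opposite directions. For the 1117 genes called in both at day 7, a set chosen after the data were seen, the mutant at day 1 had covered 39.7 ± 5.87% (n = 3) of its own day 7 change and WT 41.3 ± 18.2% (n = 2; exact permutation test, two-sided p = 1, smallest possible 0.1). At day 2 the shares were 61.2 ± 2.54% and 67.1 ± 13.3% (n = 2 each; exact p = 1, smallest possible 0.333). The WT libraries at day 1 lay at 28.4 and 54.2%.

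A further question was whether mutant cells in serum already leaned towards the 2i state. Across genes the day 0 genotype difference correlated with the WT response at r = 0.0491 (day 1) and 0.169 (day 7). Unchanged groups that share the WT day 0 libraries gave 0.50 and 0.498 in simulation, and the covariance was 0.0227 and 0.146 against 0.166 and 0.165 simulated, where the simulation holds no WT series. With 1 WT day 0 library for each contrast, r was -0.435 and -0.25 for day 1 and -0.0142 and -0.228 for day 7. Without 1 library, r ran from -0.109 (without WT day 1 replicate 2) to 0.456 (without WT day 0 replicate 2) for day 1, with 0.378 without WT day 0 replicate 1 and 0.158 without WT day 1 replicate 1. For day 7 it ran from 0.0907 (without mutant day 0 replicate 2) to 0.499 (without WT day 0 replicate 2).

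Since the polymerase elongates slowly, the genotype difference was set against gene length. The 2194 genes spanning at least 100 kb lay lower in the mutant than other genes at day 0 (median log2 -0.295 against -0.014, adjusted p = 4.23e-05) and day 1 (-0.32 against -0.012, adjusted p = 6.37e-07). At day 2 the medians were -0.0998 and -0.0022 (adjusted p = 0.0437, or 0.0645 with the WT series term and 0.238 from 50 kb), and at day 7 -0.023 and -0.027 (adjusted p = 0.831, or 0.0347 with -0.15 from 200 kb). With an estimated correlation these were adjusted p = 0.293, 0.293, 0.556 and 0.938. Long genes of low expression differed most at day 0, with -1.03 against -0.563 for shorter genes in the lowest of 5 expression classes, and -0.051 against 0.061 in the highest. Without the stromal pair the medians of long genes were -0.139 and -0.0961 at days 0 and 1.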

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

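Chosen only after the result was seen were the tests of T, mesoderm and endoderm members, chromosomes and the explanations for long genes. So were the WT series term, span offsets and leaving out the stromal pair. Singled out here are 19 results in which the set test on the difference of the 2i responses separated the genotypes for a gene list. Each had adjusted p = 0.982 with an estimated correlation, and edgeR called 0 single genes for the difference at each day, with 118, 366 and 1178 at an unadjusted p under 0.05 and 0, 0 and 73 by DESeq2.

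The 2-cell-like list, genes of the early embryo, lay higher in the mutant response at day 1 (median log2 1.09, adjusted p = 3.95e-05, or 0.31 without WT day 0 replicate 2 and 0.095 without WT day 1 replicate 1), day 2 (median log2 1.17 and 1.07 with members at their bound, adjusted p = 9.18e-06, or 0.107 without WT day 0 replicate 2 and 0.116 without WT day 2 replicate 1) and day 7 (median log2 2.05, adjusted p = 8.77e-07, 25 of 25 members positive). Several of its members are close paralogs that can share reads. Germline genes (median log2 0.36, adjusted p = 0.0101, or 0.673 without WT day 0 replicate 2, 0.988 without WT day 1 replicate 1 and 0.0927 without mutant day 1 replicate 2) and MYC targets (median log2 0.15, adjusted p = 0.000163, or 0.638 without the stromal pair, 0.0544 without WT day 0 replicate 1, 0.394 without WT day 1 replicate 1 and 0.673 without mutant day 0 replicate 2) lay higher at day 1. At day 2 core pluripotency genes lay lower (median log2 -0.23, adjusted p = 0.0149, or 0.0667 with the WT series term, 0.134 without the stromal pair, 0.0765 with span offsets, 0.192 with span offsets and WT series term, 0.123 without WT day 0 replicate 1, 0.461 without WT day 2 replicate 1, 0.199 without mutant day 0 replicate 1 and 0.0726 without mutant day 2 replicate 2), and so did ribosomal protein (median log2 -0.31 (-0.13 with span offsets), adjusted p = 0.00216, or 0.879 without WT day 2 replicate 2, 0.0976 without mutant day 0 replicate 1 and 0.717 without mutant day 2 replicate 1) and oxidative phosphorylation genes (median log2 -0.21 (-0.095 with span offsets), adjusted p = 0.0253, or 0.31 without the stromal pair, 0.137 with span offsets, 0.0584 with span offsets and WT series term, 0.307 without WT day 0 replicate 1, 0.467 without WT day 2 replicate 2, 0.085 without mutant day 0 replicate 1 and 0.809 without mutant day 2 replicate 1). Mesoderm and endoderm (median log2 1.25, adjusted p = 0.00898, or 0.338 without the stromal pair, 0.316 without WT day 0 replicate 1 and 0.0897 without WT day 2 replicate 1), fibroblast and stromal (median log2 0.895 and 1.01 with members at their bound, adjusted p = 0.02, or 0.472 without the stromal pair, 0.07 with span offsets, 0.765 without WT day 0 replicate 1, 0.101 without WT day 2 replicate 2 and 0.0844 without mutant day 0 replicate 1) and cytoskeleton genes (median log2 0.61, adjusted p = 0.0186, or 0.117 without WT day 0 replicate 1, 0.43 without WT day 2 replicate 2, 0.0502 without mutant day 0 replicate 2 and 0.108 without mutant day 2 replicate 1) lay higher there, but cytoskeleton genes lay lower without WT replicate 1 of days 0 and 1 (adjusted p = 0.0117). Splicing factors also lay higher (median log2 0.121, adjusted p = 0.0447, or 0.0586 with the WT series term and 0.652 without WT replicate 1 of days 0 and 1), with adjusted p from 0.05 to 0.575 without any 1 of 8 libraries (WT day 0 replicate 1, both of WT day 1, WT day 2 replicate 2, both of WT day 7, mutant day 0 replicate 2 and mutant day 2 replicate 1).

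By day 7 cholesterol synthesis genes lay higher in the mutant response (median log2 0.65, adjusted p = 4.68e-05, 18 of 24 members positive), and ribosomal protein genes lay lower (median log2 -0.68 (-0.29 with span offsets), adjusted p = 1.13e-08, 1 of 43 positive). Core pluripotency (median log2 -0.37, adjusted p = 0.0377, or 0.0664 with replicate number as a block, 0.112 with the WT series term, 0.119 without the stromal pair, 0.211 with span offsets, 0.365 with span offsets and WT series term, 0.121 without WT day 0 replicate 1, 0.316 without WT day 7 replicate 1, 0.19 without mutant day 0 replicate 1 and 0.0843 without mutant day 7 replicate 2), replication-dependent histone (median log2 -1.05 (-0.54 with span offsets), adjusted p = 0.00855, or 0.068 without the stromal pair, 0.211 with span offsets, 0.251 with span offsets and WT series term, 0.0625 without WT day 0 replicate 1, 0.0589 without WT day 7 replicate 2 and 0.139 without mutant day 7 replicate 1) and oxidative phosphorylation genes (median log2 -0.43 (-0.23 with span offsets), adjusted p = 0.00454, or 0.0608 without the stromal pair, 0.12 with span offsets, 0.0625 without WT day 0 replicate 1 and 0.106 without WT day 7 replicate 2) lay lower. Fibroblast and stromal (median log2 1.82 and 2.03 with members at their bound, adjusted p = 0.0253, or 0.796 without the stromal pair, 0.0561 with span offsets, 0.754 without WT day 0 replicate 1, 0.153 without WT day 7 replicate 1, 0.0712 without mutant day 0 replicate 1 and 0.0677 without mutant day 7 replicate 2) and imprinted genes (median log2 0.88, adjusted p = 0.0253, or 0.638 without the stromal pair, 0.695 without WT day 0 replicate 1, 0.3 without WT day 7 replicate 1, 0.104 without mutant day 0 replicate 2, 0.0668 without mutant day 2 replicate 1, 0.0681 without mutant day 2 replicate 2 and 0.193 without mutant day 7 replicate 2) lay higher.

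For the average genotype difference, the real split of libraries within days called 1973 genes. Of 99 others, 1 called 1703 and 98 called 0. Splits treat libraries as exchangeable within a day, which the 2 WT series put in doubt, so they cannot exclude chance. The split with 1703 set WT replicate 2 of days 0, 1 and 2 apart from replicate 1. With it went mutant replicate 1 of days 0 and 1 and replicate 2 of day 2. Each had its group's highest median of genes under 5 kb, which points to a sample structure along span. Day 7 libraries stayed by genotype, and the 9 splits with all of WT replicate 1 on one side called 0.

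Chromosome 8 genes lay higher in each of the 9 mutant libraries than in any WT library. A gene length trend between libraries is argued against as the whole cause, because the median of 0.36 over 819 genes was still 0.319 once each library's trend on span was removed. An extra copy of chromosome 8 in the mutant cultures may account for it: in 10 of 10 parts with 58 or 59 genes each the median lay above 0.1, between 0.295 and 0.458. WT replicate 2 also lay more than 0.1 above WT replicate 1 in 8 of these parts (-0.069 to 0.374). An extra chromosome 15 in the WT replicate 2 cultures stays open, with 9 of 10 such parts above 0.1 between the WT series. No other biological explanation was tested, as the labels give neither clones nor karyotypes.

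Stromal and mesoderm transcripts marked WT replicate 1 at days 0 and 1, with the fibroblast list at a mean of 3.50 and 3.64 on the log2 CPM scale against 0.57 and 0.66 in replicate 2 (24 of its 28 members passed the expression filter in these cells). Fibroblasts as the only other cells are argued against by T, which they lack, at 559 times its level in WT replicate 2 at day 0, and the cultures were feeder-free per the labels. Differentiating cells in the WT replicate 1 culture are a candidate explanation that stays open, with 14 of the 21 other mesoderm and endoderm members higher than in replicate 2 (exact two-sided binomial sign test, p = 0.189), too few to decide. No group of the design separates the replicates.

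For long genes lower in the mutant at days 0 and 1, none of 3 explanations is excluded. Slower elongation whatever the day stays open, but at day 7 long genes lay above others from 50 kb (0.0406 and -0.0544). Medians were -0.0233 and -0.0266 from 100 kb and -0.15 and -0.0224 from 200 kb. Library differences in recovery by length stay open. Over 1268 genes from 100 kb, medians differed more within groups than between genotypes at day 1 (0.333 and 0.214, against -0.205). At day 0 they did not (0.104 and 0.0514, against -0.11). Over all 2194 the day 1 median was -0.32, larger in size than 0.214. Transcripts of other cells in WT replicate 1 could add to the pattern. The day 0 median was -0.139 without the stromal pair and -0.295 with it. For the ribosomal protein genes at day 0, with the trend on span removed the median was 0.267 instead of 0.488 (adjusted p = 1.79e-05), so that part of it is left open.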

How the results depend on the processing

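Chosen only after seeing the data were the WT series term (lenient between genotypes), span offsets with and without it, and the robust prior. So was leaving out the stromal pair, chromosomes 8, 15 and Y, or Y alone. Counts of called genes are given for the genotype difference at days 0, 1, 2 and 7 (43, 64, 11 and 15), its average (1973), the WT response at days 1, 2 and 7 (31, 332 and 1955), the mutant response at the same days (216, 449 and 2176) and the difference of responses at day 7 (0). The cause of a change was not tested unless stated. With another normalisation (RLE, upper quartile), no filter, reads thinned to the smallest library or a robust prior, each of these counts stayed within 1.5 times. A stricter filter did so except at day 0 (87).

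DESeq2 gave 689, 775, 139 and 310 for the genotype difference, 2965 for its average, 321, 1221 and 3198 for WT, 805, 1220 and 3308 for the mutant and 73 for the difference of responses. With only the compared groups in the fit there were 1, 5, 0 and 0 for the genotype difference, 0, 0 and 133 for WT and 1077, 1748 and 5556 for the mutant. That fit estimates the spread from fewer libraries, which alone would not raise the mutant counts. The median SD within groups was 0.194 to 0.315 in WT and 0.124 to 0.219 in the mutant (log2). The main fit pools the groups, so its p-values may be too small for WT and too large for the mutant. Replicate number as a block gave 68 at day 0, 8 at day 7, 116 for the mutant at day 1 and 2120 for the average. A block for the WT replicates alone gave 576, 695, 42 and 191, an average of 3377, 237, 1489 and 4007 for WT, 821, 1331 and 3857 for the mutant and 14 for the difference of responses. With span offsets it gave 675, 792, 76 and 289, an average of 3744, 301, 1749 and 4458 for WT, 1057, 1523 and 4257 for the mutant and 26. The offsets alone gave 90 at day 0 and 59 for WT at day 1.

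Without the stromal pair the counts were 41 at day 1, 54 at day 7, 1220 for WT at day 7 and 509 and 872 for the mutant at days 1 and 2. There the cytoskeleton list's difference in response at day 2 turned from higher to lower (adjusted p = 0.0117, main 0.0186). Without Y-linked genes day 2 had 4, and without chromosomes 8, 15 and Y days 1, 2 and 7 had 40, 6 and 8. Of the 109 list tests past the threshold, 0 remained with an estimated correlation and 0 by fry, 108 of 123 were shared with the replicate block and 74 of 99 without the WT libraries rich in stromal transcripts.

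Long genes at day 2 no longer passed with the WT block (-0.0591, adjusted p = 0.0645) or at a limit of 50 kb (-0.0382), and at day 7 they passed at 200 kb (-0.15). With an estimated correlation their adjusted p was 0.293 at days 0 and 1 and for the average, and 0.556 at day 2. Over genes of at least 5 CPM the 2 responses correlated at 0.842 and 0.78 at days 1 and 2.

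Leaving out 1 library at a time gave 1 to 110, 10 to 241, 0 to 5 and 2 to 11 genes for the genotype difference, 1105 to 2048 for its average, 0 to 83, 36 to 252 and 742 to 1500 for WT, 1 to 113, 45 to 107 and 680 to 1099 for the mutant, and 0 to 0, 0 to 0 and 0 to 1 for the difference of responses. List tests past the threshold numbered 105 to 146. Correlations of the responses ran from 0.431 to 0.736, 0.591 to 0.722 and 0.669 to 0.748, and those of the day 0 difference with the WT response from -0.109 (without WT day 1 replicate 2, a change of sign) to 0.456 at day 1 and 0.0907 to 0.499 at day 7.

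Of 426 calls on named genes, 0 were lost with DESeq2, 1 with the WT block, 6 with RLE, 12 with upper quartile, 28 with the offsets, 29 with the replicate block, 62 without the 2 WT libraries and 147 of 329 with only the compared groups. None changed direction in these settings or without any 1 library, where the most calls lost were 137 of 270 (mutant day 0 replicate 1). Depth limits genes near the floor of about 0.03 CPM, and 2 libraries per group limit the rest: on simulated data the difference of responses at day 7 recovered 3 of 100 changes of 2-fold and 31 of 100 of 4-fold.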

Other observations

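No explanation is tested in this part, and the genes below follow the rule fixed beforehand. The cell cycle list passed for no 2i response. By day 7 Ccne1, the cyclin of S phase entry, had fallen in WT (2.87-fold, adjusted p = 0.0015) and the mutant (2.75-fold, adjusted p = 0.00116), and Ccnd2 fell in the mutant (18.4-fold, adjusted p = 0.00681). The imprinted genes Dlk1 (21.1-fold and 9.84-fold lower) and Plagl1 (20.6-fold and 77.85-fold higher) moved apart in both genotypes.

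Of 38 germline genes 2 rose and 6 fell in WT by day 7 (adjusted p = 0.259 for the set), and 3 rose and 7 fell in the mutant (0.255). Ddx4, the germ cell RNA helicase, fell in WT (6.72-fold, adjusted p = 0.0015), and Dazl, an RNA-binding protein of germ cells, rose in the mutant (5.86-fold, adjusted p = 0.00178). Between the genotypes on average, Fanca, of the Fanconi repair pathway (1.47-fold, adjusted p = 0.00283), and Rbl2, the pocket protein p130 (1.90-fold, adjusted p = 0.00239), both on chromosome 8, were higher in the mutant, and Tet3, a 5-methylcytosine dioxygenase (1.87-fold, adjusted p = 0.017), was lower.

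Of the 30 lists, 7 passed in 0 of the 14 comparisons. Their smallest adjusted p were 0.125 for neuroectoderm, 0.104 for DNA methylation machinery, 0.148 for replication stress and DNA repair, 0.0823 for G1 S and G2 M regulators, 0.156 for RNA polymerase II subunits, 0.225 for elongation and termination factors and 0.195 for the integrated stress response and heat shock.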
